A study of Caenorhabditis elegans with 8 samples.

How the data were processed

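RNA was measured in Caenorhabditis elegans of the laboratory wild type N2 and of the strain FAS43, in which the genes of the replacement histone H3.3 are mutated. Mixed-stage embryos and larvae of the first stage (L1) were grown at 20 °C. There were 4 groups with 2 libraries each, 8 libraries in all. Per the labels' protocols, RNA was extracted with Trizol, stranded mRNA libraries were made from 1000 ng of total RNA with a TruSeq kit, and reads of 50 bases were sequenced on a HiSeq instrument. Nothing in the labels says whether the libraries of a group came from separate cultures. The p-values below therefore rest on the spread between these libraries, which may be technical and which the fit shared over genes.

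The deposited data were one table per stage. Each held raw counts per gene for its 4 libraries, made by the authors and not normalized. Per the submitters' processing notes, TopHat2 2.0.13, HTSeq 0.6.1 and edgeR 3.10.5 were used with the genome build WBcel235; the role and settings of each tool, the strand setting included, are not given in the sources used here. The deposited tables also held a normalized signal per library, per the file headers a normalized count. Within each library it equalled the raw count divided by a constant, and that constant was close to the TMM effective library size computed here. Per the file headers, the authors also deposited a log2 fold change of FAS43 over N2, a log2 mean abundance, a p-value and a p-value adjusted for the false discovery rate for each gene. A further deposited column marked genes as significant, and all marked genes had an unadjusted p-value under 0.05. Only the raw counts were tested here. The embryo table listed 13692 genes, 16249 genes were listed for L1, and 13335 genes were in both. Every listed gene had at least 10 counts in at least 2 libraries, so genes below that level were not analysed here.

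Totals ran from 17408914 to 30127179 counts per library. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (13617 in embryos and 16099 in L1), libraries were scaled with TMM factors, and each stage was fitted alone with genotype as the only term by the quasi-likelihood F-test, with 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called. Standard errors (SE) were taken as the absolute log2 fold change over the square root of F. Normalized read counts (CPM) use TMM effective library sizes and are given as mean ± SD. The fit shares the spread over genes, so an SE or p-value reflects a gene's own libraries only in part. In embryos rpoa-1 had 133.5 ± 9.83 CPM in N2 and 98.3 ± 3.68 CPM in FAS43, with an SE of 0.641. The more uneven his-74 had 90.3 ± 61.2 and 72.9 ± 13.3 CPM, with an SE of 0.637. The difference of the genotype effect between stages, and L1 against embryo in N2, were tested in one fit of all 8 libraries over the 13335 shared genes. Gene lists were compared with all other tested genes with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the lists. Of 32 lists, the H3.3 list was not tested by camera, and lists with fewer than 4 tested genes were left out. Intervals of count ratios are exact 95% binomial intervals. They and the floor of 3 counts, taken over the group, cover counting error only.

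Before the data were examined, the tests, the lists, the alternatives and a rule for naming genes were fixed. The rule took, per stage, the H3.3 genes in every library, the 6 largest changes in each direction among called genes with a mean CPM of at least 5, a symbol that is not a sequence name and no overlap between genotypes, and the called member of each list with a mean CPM of at least 1 and the largest change. For the interaction it took the largest called differences. It named 0 genes beyond the H3.3 genes in embryos and 0 in L1. The other genes named below were chosen after their values were seen: Y75B8A.33 and Y49E10.36 for their place beside his-72, ora-1, members called over a list alone, and from each list called by camera the members with the smallest p.

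The procedures were tested on simulated counts drawn for the real genes, with 200 genes changed. In the embryo simulation of 13257 tested genes, edgeR recovered 0% of genes changed 2-fold, 28% of those changed 4-fold, 76% at 8-fold and 100% at 32-fold, with 5 false calls. In the L1 simulation of 15822 genes these shares were 8%, 32%, 76% and 100%, with 5 false calls. For the interaction, over 13333 genes, they were 0%, 4%, 14% and 86%, with 1 false call. For L1 against embryo in N2, over 13334 genes, they were 0%, 18%, 74% and 100%, with 3 false calls. DESeq2 made 30 false calls in the embryo simulation of 13617 genes and 28 in the L1 simulation of 16099, so genes called by DESeq2 alone are less certain. At the preset correlation, camera called the 2 lists that had been moved and 0 others in both stages. Genes were drawn independently in the simulation, so it does not check camera on lists whose genes move together. The recovered shares and false calls of edgeR and DESeq2 also hold for that setting alone. In the real embryo libraries the first principal component held 66.5% of the variance. Camera with an estimated correlation, which rests on 2 residual degrees of freedom per stage, was not simulated, so its power is unknown. The alternatives were RLE and upper quartile scaling, a filter at a CPM of 1 in 2 libraries, no filter, DESeq2 1.42.0, one fit of all 8 libraries, an adjusted p under 0.01, a 2-fold minimum, a replicate block, leaving out each library and, for camera, a correlation estimated from the residuals. Chromosomes, positions and biotypes came from the annotation of WBcel235, which held 13581 of the embryo identifiers and 16108 of the L1 identifiers. No genome sequence was used here, so GC content was not examined. Plots were drawn with matplotlib 3.10.9.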

Results

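The series asked how the genes of histone H3.3, the variant of histone H3 that is placed in chromatin outside of replication, are used in C. elegans and how they bear on the response to temperature stress. All libraries analysed here were grown at 20 °C. FAS43 carries mutations in his-69, his-70, his-71, his-72 and his-74. It was compared with N2 in mixed-stage embryos and in L1 larvae, with 2 libraries per genotype and stage. The N2 embryo libraries held 30127179 and 24976442 counts and the FAS43 embryo libraries 17408914 and 27254898. The N2 L1 libraries held 28974428 and 19013469 counts and the FAS43 L1 libraries 25192440 and 24091919. Transcripts of ribosomal RNA genes took between 0.753% and 4.18% of counts, with the higher share in replicate 2 of each of the 4 groups.

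The H3.3 genes were examined first in each library. In N2 embryos his-72 was the most abundant of the listed H3.3 genes, at 1612 ± 850 CPM (SD, n = 2), against 94.1 ± 6.03 CPM for his-71 and 90.3 ± 61.2 CPM for his-74. FAS43 embryos held 1.32 ± 0.0633 CPM of his-72 and 0.107 ± 0.0180 CPM of his-71. The raw counts were 59440 and 25296 in N2 against 29 and 32 in FAS43 for his-72, and 2412 and 2461 against 2 and 3 for his-71. The log2 fold changes were -10.25 (SE 0.937, edgeR adjusted p = 1.163e-23) for his-72 and -9.70 (SE 1.02, edgeR adjusted p = 1.22e-17) for his-71. For his-71 the N2 to FAS43 ratio was 869 with a 95% counting interval from 372 to 2678. His-74 had 72.9 ± 13.3 CPM in FAS43 embryos, a log2 fold change of -0.31 (SE 0.637, edgeR adjusted p = 0.9999), and its sign turned to 0.63 without N2 embryo replicate 1. The labels do not say what the his-74 allele removes, so its counts do not check the genotype.

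In L1 larvae his-72 had 477 ± 180 CPM in N2 and 5.61 ± 2.74 CPM in FAS43 (n = 2 each), and his-71 had 181 ± 47.4 against 0.252 ± 0.0388 CPM. Their log2 fold changes were -6.41 (SE 0.840, edgeR adjusted p = 0.0001209) and -9.47 (SE 0.873, edgeR adjusted p = 1.936e-07). His-70 was listed in L1 alone, with 13 and 41 counts in N2 and 0 and 0 in FAS43. It was at least 17.4-fold lower in FAS43 against the floor of 3 counts over the group; its edgeR adjusted p was 0.2536 over all genes and 9.15e-05 adjusted over the list alone. His-74 had 12.97 ± 3.86 CPM in N2 and 20.96 ± 9.81 CPM in FAS43, which did not pass the test (edgeR adjusted p = 0.9996). His-69 was listed in neither table and was not analysed here. Adjusted over the list alone, 2 H3.3 genes were called in embryos and 3 in L1, against 2 and 2 over all genes. His-72 lies on chromosome III from 12367475 to 12369050, his-71 on X from 7981382 to 7982070, his-74 on V from 12659704 to 12660330 and his-70 on III from 4059715 to 4060119 (WBcel235).

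**Figure D1:**
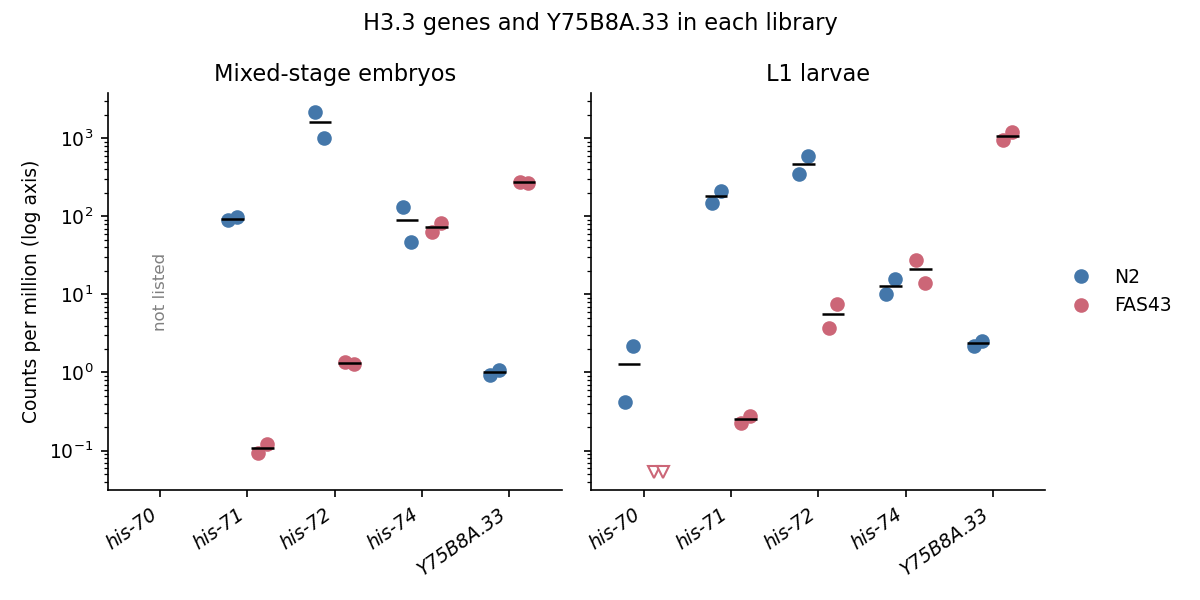
CPM on a log axis for 4 H3.3 genes and Y75B8A.33 in each library, with 1 point per library and a bar at the mean of each pair; open triangles stand for 0 counts. His-71 and his-72 sit far lower in both FAS43 libraries than in both N2 libraries, Y75B8A.33 sits higher, and his-74 overlaps between genotypes in embryos.

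The use of the H3.3 genes by wild-type animals was compared between stages in the fit of all 8 libraries. His-74 was lower in N2 L1 than in N2 embryos, by a log2 fold change of -2.66 (SE 0.639, edgeR adjusted p = 0.004166), from 85.8 ± 62.2 to 13.6 ± 4.16 CPM in that fit. His-72 had a log2 fold change of -1.61 (SE 0.655, edgeR adjusted p = 0.0586) and his-71 one of 1.118 (SE 0.510, edgeR adjusted p = 0.08861), neither past the threshold over all genes. Adjusted over the list alone, all 3 genes were called, at 0.001698 for his-74, 0.03602 for his-72 and 0.04162 for his-71 (edgeR). The number called over all genes was 1, and it was 0 without N2 embryo replicate 1, 2 without N2 embryo replicate 2 and 2 with DESeq2. The tables were counted separately for each stage, so levels set across stages assume that both were counted alike.

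Outside the H3.3 genes, the same gene was called in both stages. Y75B8A.33, a protein-coding gene with a sequence name, chosen after its values were seen, was higher in FAS43. In embryos it had 25 and 27 counts in N2 against 5917 and 6741 in FAS43, that is 1.00 ± 0.105 against 274 ± 6.94 CPM, and a log2 fold change of 8.08 (SE 0.885, edgeR adjusted p = 3.088e-16). In L1 it had 69 and 48 counts in N2 against 25213 and 25639 in FAS43, and a log2 fold change of 8.80 (SE 0.987, edgeR adjusted p = 7.533e-06). Y75B8A.33 lies on the minus strand of chromosome III from 12361838 to 12367373. His-72 lies beside it on the same strand, from 12367475 to 12369050. Log2 ratios of Y75B8A.33 in FAS43 over N2 within equal replicate numbers were 7.61 and 7.42 in embryos and 8.44 and 8.61 in L1. They have 0.5 CPM added to each value, which makes them smaller. The snoRNA Y49E10.36, annotated inside his-72 from 12368319 to 12368544, had 33 and 25 counts in N2 L1 against 277 and 249 in FAS43 L1, a log2 fold change of 3.20 (SE 0.716, edgeR adjusted p = 0.3044). It was called with DESeq2 (log2 fold change 3.22, adjusted p = 0.000788), and its adjusted p ran from 0.000788 to 1 over the alternatives. It shares its place with his-72, so its counts are uncertain.

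**Figure D2:**
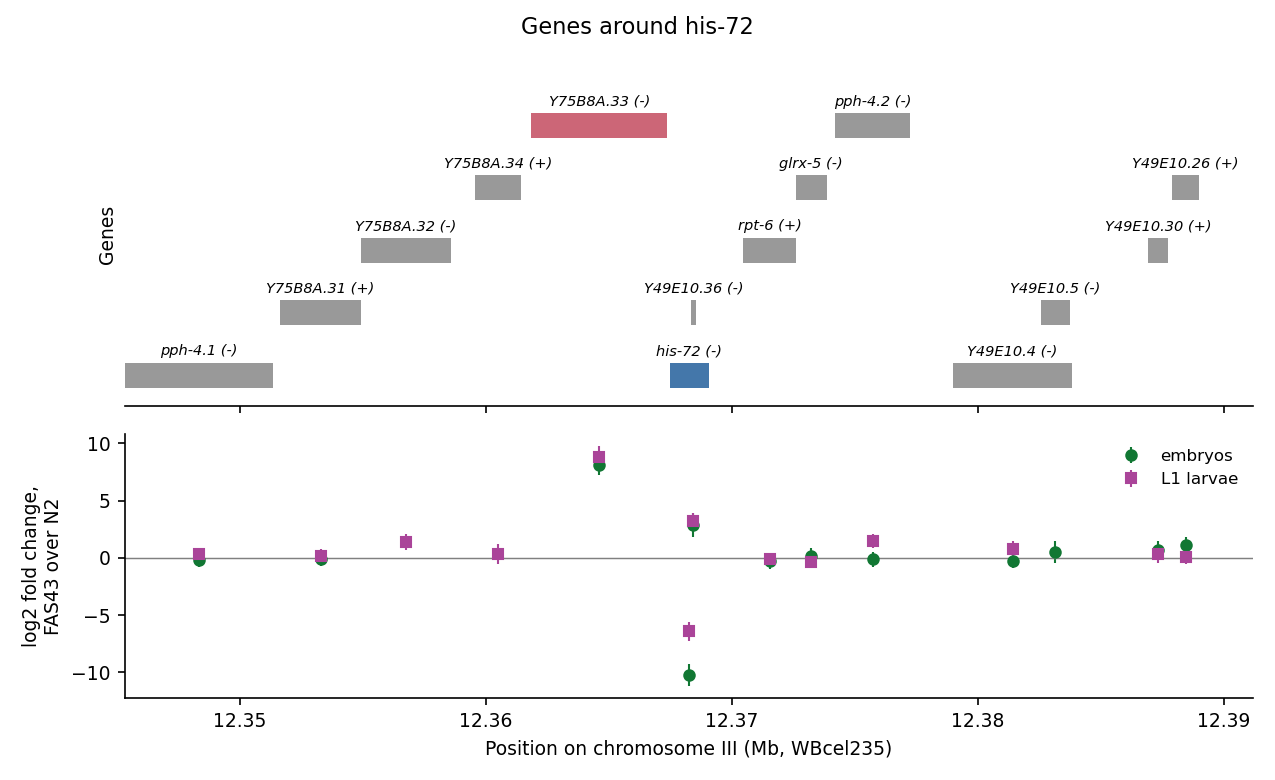
Map of chromosome III around his-72 (WBcel235, position in Mb) with gene spans and strands above, and below them the log2 fold change of FAS43 over N2 for each tested gene in embryos (circles) and L1 (squares) with its SE. Y75B8A.33 stands at 8.08 and 8.80 beside his-72 at -10.25 and -6.41, and the snoRNA Y49E10.36 inside his-72 at 2.88 and 3.20. The other genes drawn lie within -0.35 to 1.46.

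In embryos, 1 gene was called higher (Y75B8A.33) and 2 lower (his-71 and his-72) among 13617 tested with edgeR. DESeq2 gave the same numbers. Unadjusted p-values under 0.05 were found for 95 genes, fewer than the 681 that uniform p-values would give. The count higher was 21 without N2 embryo replicate 2, and the count lower was 5 without N2 embryo replicate 1. The authors' deposited table marked 84 genes, 70 higher and 14 lower, and 3 had a false discovery rate under 0.05. Of the marked genes, 82 had an unadjusted p under 0.05 here.

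Of 30 gene lists tested in embryos with camera, 4 lay higher and 7 lower in FAS43 relative to other genes at the preset correlation. None held with an estimated correlation (adjusted p = 0.981 for each of them), and splits of the same 4 libraries that mix the genotypes called 20 and 15 lists against 11 for the real one. Neuropeptide genes had a median log2 fold change of 0.77, with 89 of 95 members positive (camera adjusted p = 2.2e-27). Cuticle collagens had a median of 0.50, with 73 of 95 positive (camera adjusted p = 8.74e-16), and immune and antimicrobial genes one of 0.62, with 32 of 42 positive (camera adjusted p = 1.04e-12). The median of C-type lectins was 0.17 (camera adjusted p = 0.000667). Of the 11 lists, 0 kept their call whichever library was left out, and the direction of collagens and C-type lectins turned. Single members were uneven within FAS43: the neuropeptide gene snet-1 had 92 and 9 counts in FAS43 against 3 and 31 in N2, and cnc-4, of the antimicrobial caenacins, had 631 and 141 against 39 and 209. No member was called over all genes. Adjusted over the list alone, lys-3, a lysozyme gene, was called with a log2 fold change of 3.303 (edgeR adjusted p = 0.0404), from 135 and 17 counts in FAS43 against 5 and 13 in N2, and its log2 fold change was 0.938 without FAS43 embryo replicate 1. In the list of molting genes, which camera did not call (adjusted p = 0.394), grl-21 was called over the list alone (log2 fold change 3.32, edgeR adjusted p = 0.0121), from 353 and 22 counts in FAS43 against 5 and 39 in N2, and its log2 fold change was 0.012 without FAS43 embryo replicate 1.

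Replicative histone genes, whose histones are made during DNA synthesis, had a median log2 fold change of -0.61 in embryos, and 30 of 30 tested members were negative (camera adjusted p = 1.06e-06, and 0.981 with an estimated correlation). His-60 had 40.8 ± 25.9 CPM in N2 and 23.2 ± 1.72 CPM in FAS43, with 1588 and 563 counts in N2, so 1 N2 library stood above the rest. Without N2 embryo replicate 1 the direction of this list turned. Many replicative histone genes are near-identical copies, and how fully the mRNA libraries captured their RNA was not examined, so their counts are uncertain. The medians of the other lists called lower were -0.20 for chromatin and small RNA silencing factors (camera adjusted p = 0.00298), -0.09 for oocyte and germline genes (0.00256), -0.30 for ciliary genes (0.0226), -0.20 for nucleolar genes (0.0241) and -0.14 for DNA damage genes (0.0469). Each of these had an adjusted p = 0.981 with an estimated correlation. The median of all genes was -0.08. The medians of oocyte, nucleolar and DNA damage genes reached 0.12, 0 and 0.06 with the CPM filter. That filter moved the median of all genes by 0.20, so these moves were shared by other genes. Each of these 5 lists turned direction without some library. The other 19 lists had camera adjusted p-values of 0.0645 or more.

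Heat shock genes, which encode chaperones induced by heat, had a median of -0.40 in embryos, with 20 of 28 members negative (camera adjusted p = 2.49e-06, and 0.981 with an estimated correlation). Adjusted over the list alone 3 members were called, and 0 over all genes. They were hsp-70 (log2 fold change -2.64, SE 0.716, edgeR adjusted p = 0.00654), F44E5.4 (-2.32, edgeR adjusted p = 0.0191) and F44E5.5 (-2.21, edgeR adjusted p = 0.0191). The counts of hsp-70 were 464 and 2727 in N2 against 224 and 244 in FAS43. Without N2 embryo replicate 2 the log2 fold changes were -0.55, -0.20 and -0.10 for hsp-70, F44E5.4 and F44E5.5. In L1 the list had a median of -0.44, with 23 of 29 members negative (camera adjusted p = 0.000344, and 0.654 with an estimated correlation). The list lost its call without N2 L1 replicate 2, where its signed -log10 p went from -3.91 to -0.53, and without FAS43 L1 replicate 2. Adjusted over the list alone, 4 members were called in L1, and 0 over all genes; hsp-70, at -0.81 in L1, was not among them. The small heat shock gene hsp-16.41 had 3651 and 2936 counts in N2 against 691 and 384 in FAS43, a log2 fold change of -2.65 (SE 0.618, edgeR adjusted p = 0.00553 over the list alone and 0.3839 over all genes). It was called over all genes with DESeq2 (log2 fold change -2.63, adjusted p = 0.00709), and its adjusted p ran from 0.00709 to 1 over the alternatives. For hsp-16.2 the log2 fold change was -2.09 (edgeR adjusted p = 0.0343 over the list alone). In embryos hsp-16.41 and hsp-16.2 had log2 fold changes of -1.39 and -1.39, not called (edgeR adjusted p = 0.9999). Their log2 ratios between the embryo libraries numbered 1, with 0.5 CPM added to each value, were -0.024 and 0.046. In L1 F44E5.4 and F44E5.5 (both edgeR adjusted p = 0.0288 over the list alone) had log2 fold changes of -2.46 and -2.49. These were -0.64 and -0.68 without N2 L1 replicate 2. F44E5.4 and F44E5.5 are close copies of each other, as are genes of the hsp-16 family, so their single values are uncertain.

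**Figure D3:**
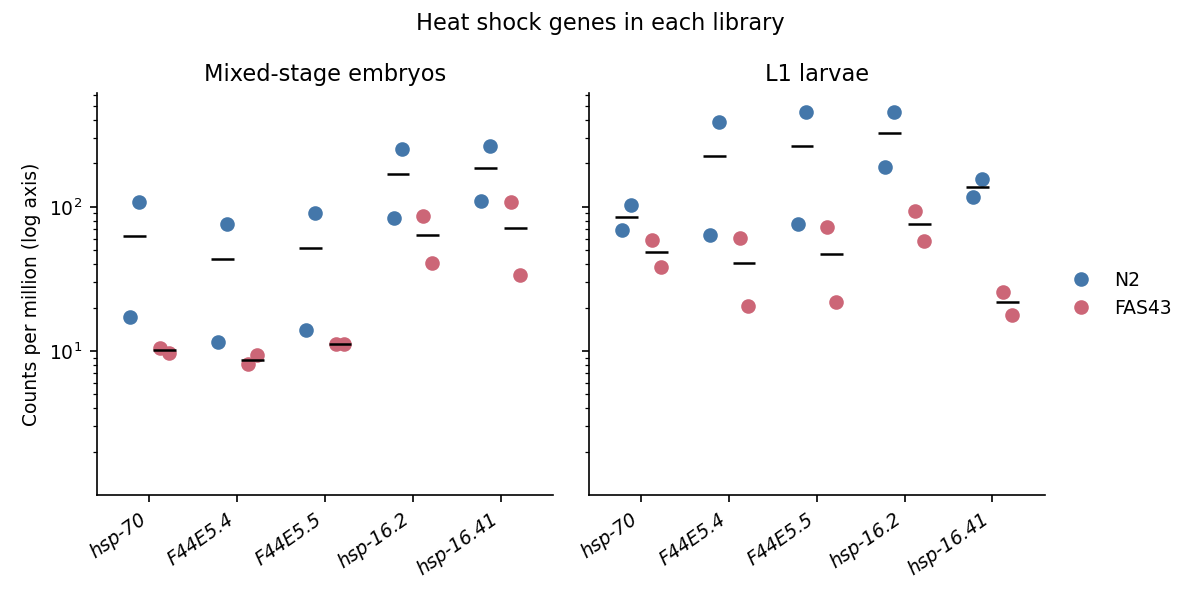
CPM on a log axis for 5 heat shock genes in each library, with 1 point per library and a bar at the mean of each pair. In embryos 1 N2 library stands apart for hsp-70, F44E5.4 and F44E5.5. In L1 both N2 libraries lie above both FAS43 libraries for all 5 genes. The gap is small for F44E5.4 (63.8 CPM in N2 replicate 1 against 61.1 CPM in FAS43 replicate 1). The same libraries lie close for F44E5.5 (75.6 against 72.4 CPM) and hsp-70 (68.7 against 59.1 CPM).

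In L1 larvae 1 gene was called higher (Y75B8A.33) and 2 lower (his-71 and his-72) among 16099 tested with edgeR. DESeq2 gave 2 higher and 4 lower, adding Y49E10.36, hsp-16.41 and ora-1. Unadjusted p-values under 0.05 were found for 543 genes, against 805 under uniform p-values. Without FAS43 L1 replicate 1 the counts were 3 higher and 19 lower. The authors' deposited table marked 579 genes, 308 higher and 271 lower, and 3 had a false discovery rate under 0.05. Of these marked genes, 537 had an unadjusted p under 0.05 here. Ora-1 had 195 and 915 counts in N2 against 87 and 22 in FAS43, a log2 fold change of -3.67 (SE 0.798, edgeR adjusted p = 0.2536). Without N2 L1 replicate 2, the library with 915 counts, its log2 fold change was -1.54. It was called without FAS43 L1 replicate 1 (adjusted p = 0.0017) and without N2 L1 replicate 1 (adjusted p = 0.0213), while its adjusted p ran from 0.00105 to 1 over the alternatives.

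Of 31 lists tested in L1 with camera, 7 lay higher and 11 lower in FAS43, and none held with an estimated correlation. Splits of the same 4 libraries that mix the genotypes called 15 and 20 lists, against 18 for the real one. Replication and cell cycle genes had a median log2 fold change of 1.05, and 60 of 61 members were positive (camera adjusted p = 9.06e-20, and 0.578 with an estimated correlation). The signed -log10 p of this list was 20.53, and 2.45 without FAS43 L1 replicate 1. The cyclin B gene cyb-2.2 had 5.67 ± 3.25 CPM in N2 and 21.6 ± 11.6 CPM in FAS43 (log2 fold change 1.93, SE 0.646), and cyb-2.1 a log2 fold change of 1.75, neither called. Oocyte and germline genes had a median of 0.74, with 49 of 57 positive (camera adjusted p = 9.37e-15, and 0.578 estimated). Among them mex-6 and oma-1, which act in the oocyte and early embryo, were not called. Mex-6 had 1308 and 187 counts in N2 against 4556 and 1328 in FAS43, and oma-1 had 15.5 ± 9.28 against 60.9 ± 42.9 CPM. Early zygotic regulators had a median of 0.75 (camera adjusted p = 6.83e-08, and 0.578 estimated), with pes-10 at 4.38 ± 3.03 against 17.8 ± 13.3 CPM, and its signed -log10 p went from 7.81 to 1.47 without FAS43 L1 replicate 1. Chromatin and small RNA silencing factors had a median of 0.74, with 46 of 47 positive (camera adjusted p = 4.08e-13, and 0.578 estimated). The Argonaute genes wago-1 and ergo-1 had log2 fold changes of 1.46 and 1.40. Histone chaperones and other variants had a median of 0.78 (camera adjusted p = 3.43e-05, and 0.578 estimated), with the chaperone gene nasp-2 at 1.88. DNA damage genes had a median of 0.52 (8.87e-07, and 0.582 estimated) and nucleolar genes one of 0.37 (0.000607, and 0.578 estimated). None of the members named here was called, and without FAS43 L1 replicate 1 their log2 fold changes were 0.66 for wago-1, 0.76 for ergo-1, 0.82 for nasp-2, 1.24 for mex-6, 0.97 for oma-1, 0.92 for pes-10, 1.23 for cyb-2.2 and 1.22 for cyb-2.1.

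Cuticle collagens had a median log2 fold change of -0.82 in L1, and 131 of 143 members were negative (camera adjusted p = 8.04e-19, and 0.578 with an estimated correlation). The signed -log10 p of the list was -19.28, and -1.98 without N2 L1 replicate 2, the library that stood apart on the first principal component. Col-130 had 95.1 ± 71.3 CPM in N2 and 21.7 ± 2.49 CPM in FAS43. Genes of cytochrome P450, UGT and GST enzymes, which act in detoxification, had a median of -0.57 with 130 of 171 negative (camera adjusted p = 1.61e-11, and 0.51 estimated). Oxidative and xenobiotic stress genes had a median of -0.38 (camera adjusted p = 1.35e-05, and 0.578 estimated), with gst-5 at 260 ± 101.3 against 64.1 ± 31.4 CPM. One member, cyp-35C1, was called over the list alone (log2 fold change -2.55, edgeR adjusted p = 0.0407), from 538 and 1435 counts against 328 and 80; without N2 L1 replicate 2 its log2 fold change was -1.11. Chemoreceptor genes had a median of -0.57, with 169 of 207 negative (camera adjusted p = 8.98e-11, and 0.578 estimated), and a signed -log10 p of -10.76 that was -1.9 without N2 L1 replicate 1. Immune and antimicrobial genes had a median of -0.47 (0.000607, and 0.654 estimated), while their member clec-60 had a log2 fold change of 3.02 from 11 and 9 counts in N2 against 91 and 72 in FAS43, not called (edgeR adjusted p = 0.9996). Sperm genes had a median of -0.66 (0.0152, and 0.615 estimated) and replicative histone genes one of -0.50 (0.014, and 0.898 estimated). The medians were -0.27 for ciliary genes (0.014, and 0.772 estimated), -0.24 for neuropeptides (0.00112, and 0.902 estimated) and -0.19 for osmotic stress genes (0.0328, and 0.578 estimated). The other 13 lists had camera adjusted p-values of 0.06 or more. Median, mean and test differed in sign only among lists that camera did not call, such as early zygotic regulators and intestine genes in embryos and molting and intestine genes in L1. Of the 18 lists, 10 kept their call and direction whichever library was left out. Histone chaperones, heat shock genes, immune genes, neuropeptides, replicative histone genes, ciliary genes, sperm genes and osmotic stress genes lost theirs without some library.

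**Figure D4:**
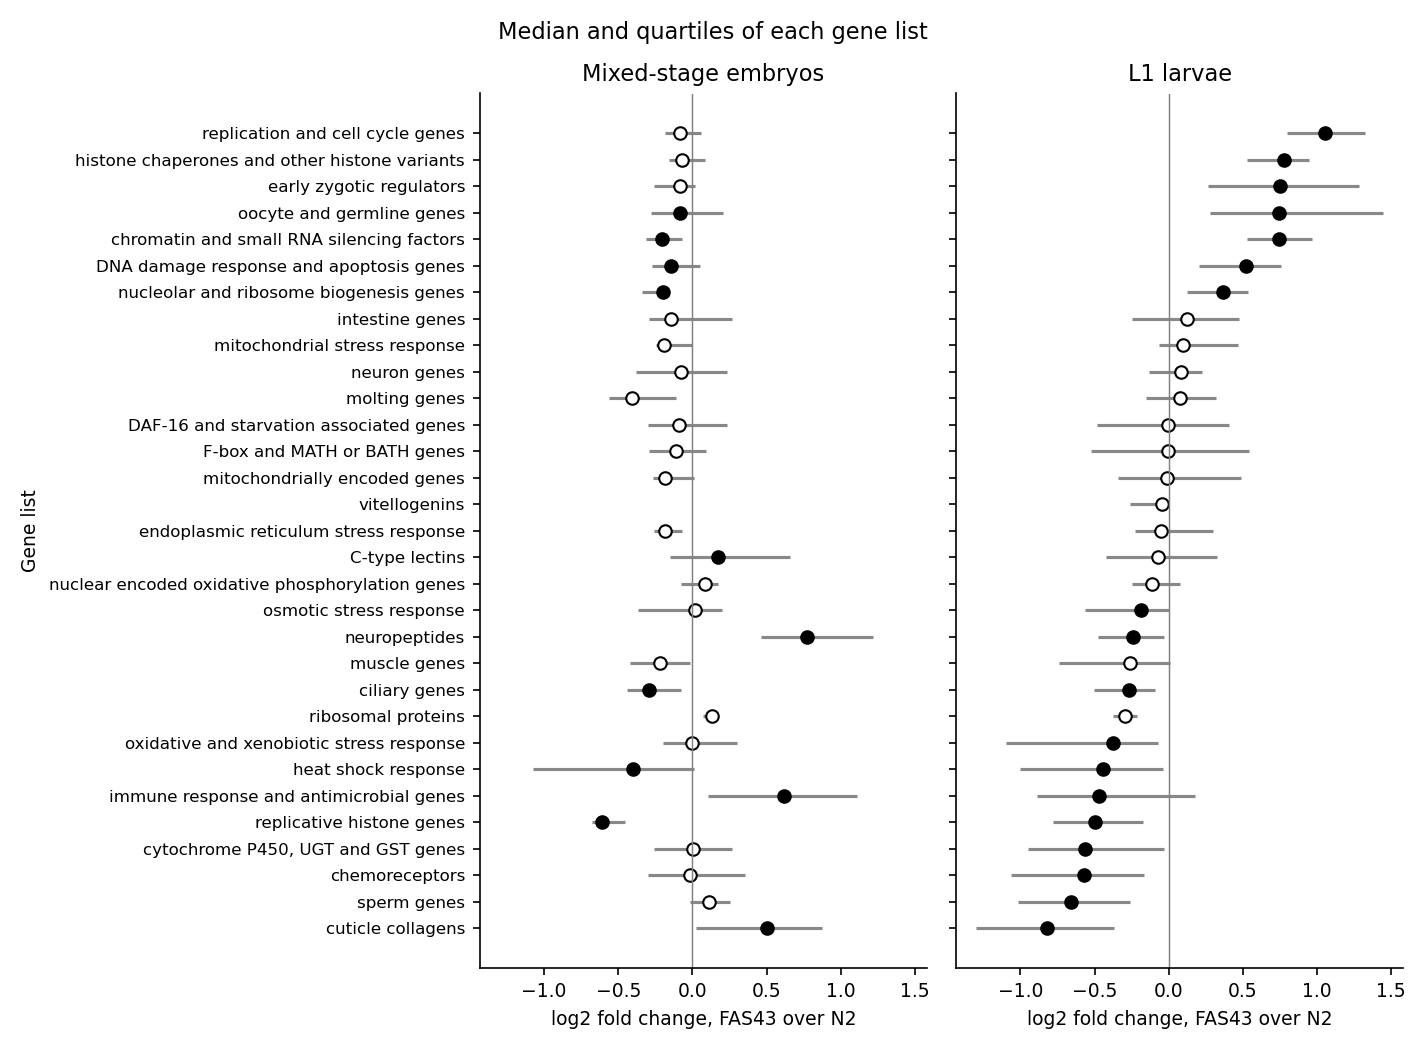
Median log2 fold change of FAS43 over N2 (points) with quartiles (lines) for each gene list in embryos and in L1; filled points mark lists called by camera at the preset correlation. In L1 replication and cell cycle genes stand at 1.05 and cuticle collagens at -0.82.

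The effect of FAS43 was compared between stages. Y75B8A.33 was called higher in both stages (1 shared gene), and his-71 and his-72 lower in both (2 shared). The 2 genes called lower are mutated in FAS43, so their overlap was set by the strain. Across 13256 genes, which are not independent replicates, the log2 fold changes of the stages had a correlation of -0.146, and -0.218 without the called genes. The interaction test called 0 of 13335 genes with edgeR and 0 with DESeq2, and 199 genes had an unadjusted p under 0.05 against 667 from uniform p-values. For his-72 the log2 fold change was less negative in L1, with a difference of L1 minus embryo of 3.71 (SE 0.953). Its edgeR adjusted p was 0.9986 over all genes and 0.003073 adjusted over the list alone. The his-72 counts left in FAS43 were 29 and 32 in embryos and 98 and 162 in L1. From embryo to L1 the log2 ratio of his-72 was 2.1 in FAS43 and -1.61 in N2, and that of Y75B8A.33 in FAS43 was 1.97. The difference therefore combines a lower N2 level in L1 with a rise of the few counts left of a mutated gene.

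The FAS43 alleles lie on chromosomes III, V and X. Of the 3 called genes in each stage, 2 lie on III and 1 on X, places set by the mutated genes and the neighbour of his-72, so a test of called genes per chromosome says nothing here. Among genes with an unadjusted p under 0.05, chromosome V held 30 of 95 in embryos (Fisher's exact test, adjusted p = 0.00851) and 152 of 538 in L1 (adjusted p = 0.000397), where genes of the mitochondrial genome or without an annotated chromosome were left out of the 543. Chromosome III held 48 of these 538 in L1, a lower share than the rest (Fisher's exact test, adjusted p = 0.000397). These genes did not pass the adjusted threshold, and neighbouring genes are not independent.

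Libraries of the same group differed widely. In embryos 5509 genes differed more than 2-fold between the N2 libraries and 3934 between the FAS43 libraries, but 1133 between N2 replicate 1 and FAS43 replicate 2. The first principal component held 66.5% of the variance in embryos and set N2 replicate 2 and FAS43 replicate 1 apart from the other two. In L1, 4521 genes differed more than 2-fold between the N2 libraries and 4966 between the FAS43 libraries. The first principal component held 49.4% of the variance in L1 and set N2 replicate 2 apart. That library differed more than 2-fold from the FAS43 libraries at 5463 and 5408 genes, against 3321 and 2181 for N2 replicate 1. The chi-square per degree of freedom between libraries of a group was 191 or more, so no pair was the same library.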

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

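The tests on Y75B8A.33 and on his-71 below were chosen only after the results were seen, as was the camera test of the interaction. By a test of the difference, the FAS43 effect on his-72 differed between the stages over the H3.3 list alone (3.71 on the log2 scale, L1 minus embryo). The FAS43 side of that value was the few counts left of a mutated gene. The FAS43 effect also differed for 16 of 30 gene lists by camera at the preset correlation, none of them with an estimated correlation (lowest adjusted p = 0.562). Groups of 2 libraries were too small for a formal test of a single library far from the rest of its group.

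Lists that lay higher in FAS43 in L1 than in embryos, with camera adjusted p of the difference, were replication and cell cycle genes (1.28e-13), oocyte and germline genes (5.08e-13), chromatin and small RNA silencing factors (7.83e-13), DNA damage genes (6.66e-06), early zygotic regulators (0.000211), nucleolar genes (0.000211) and histone chaperones (0.00585). Lists with the opposite difference were cuticle collagens (7.07e-22), neuropeptides (3.8e-16), immune genes (1.51e-08), cytochrome P450, UGT and GST genes (2.43e-08), oxidative stress genes (6.72e-05), chemoreceptors (9.83e-05), ribosomal proteins (0.00164), osmotic stress genes (0.0193) and C-type lectins (0.0194).

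The rise of Y75B8A.33 beside his-72 has 3 explanations that were weighed. Reads of intact his-72 mRNA counted to the neighbour would be most frequent in N2, the opposite of the pattern itself. The lowest FAS43 level was 249 times the highest N2 level, which restates that pattern and is no separate evidence. A change of the whole region is opposed by the tested genes within 50000 bases other than Y49E10.36 inside his-72, whose upper quartile of log2 fold changes was 0.38 in the stage where it was higher. Transcription running from the mutated his-72 locus into the neighbour may account for both genes and stays open. The his-72 counts left in FAS43 were 4.9, 4.75, 3.89 and 6.32 per 1000 counts of Y75B8A.33. In FAS43 the L1 over embryo log2 ratio was 1.97 for Y75B8A.33 and 2.1 for his-72, a similar rise. In N2 that ratio was -1.61 for his-72 and 1.42 for Y75B8A.33, the latter from few counts. This explanation predicted that the ratio of Y75B8A.33 in FAS43 would follow that of his-72 in N2, if both RNAs are equally stable. The prediction was not met, with a difference of 3.58. That difference could also come from unequal RNA stability, which was not measured, so the test could not rule the explanation out. Counts per gene do not show where reads lie. An effect of H3.3 loss on Y75B8A.33 itself is untested.

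Within the embryo and L1 groups, libraries differed as much as the genotypes did, and the list differences may follow the age of the animals. Swapped labels are opposed by his-71, whose lowest N2 embryo CPM was 750 times the highest FAS43 CPM, a ratio that rests on 2 and 3 counts in FAS43 (95% counting interval of the group ratio from 372 to 2678). Library size is opposed by thinning: the split of N2 replicate 2 and FAS43 replicate 1 from the other embryo libraries called 1759 genes, and 977 after thinning to equal totals. Age in the embryo mix was in line with its prediction: across genes, the L1 minus embryo difference of other libraries correlated with replicate 2 minus 1 in N2 (r of 0.678) and with replicate 1 minus 2 in FAS43 (r of 0.555). In L1 the FAS43 minus N2 difference correlated with that axis at -0.445 and -0.177 with either N2 library, so whether the FAS43 larvae were younger, or held embryos, or differed by genotype cannot be told apart with 2 libraries per group.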

How the results depend on the processing

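Crossed numbers were added as an alternative after the data were seen; the others were planned. The interaction count stayed at 0 under every alternative run, the overlap stayed at 3 under every planned one, and his-71, his-72 and Y75B8A.33 stayed called in both stages under each of them. Upper quartile scaling moved the median of all genes by 0.15 in embryos and -0.18 in L1, and the CPM filter moved it by 0.20 in embryos. With DESeq2 the L1 calls were 2 higher and 4 lower and the H3.3 genes called between stages were 2. With an estimated correlation 0 lists were called in embryos and 0 in L1. The replicate numbers were not taken to pair the libraries (correlation of deviations -0.52 in embryos and -0.181 in L1), although the share of ribosomal RNA was higher in replicate 2 of each group. With the replicate block the calls were 1 higher and 2 lower in each stage, 0 for the interaction, 3 shared, and 11 and 18 lists. Crossed numbers as a block gave 16 higher and 2 lower in embryos and 2 higher and 4 lower in L1, with 4 shared.

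Leaving out 1 library, where a lone library is assumed to vary like the others, gave 1 to 21 genes higher and 2 to 5 lower in embryos, 1 to 3 higher and 2 to 19 lower in L1, 13 to 21 lists in embryos and 15 to 21 in L1, and 0 to 2 H3.3 genes between stages. Results that turned direction in embryos ranged, in log2 fold change, from -0.66 to 0.63 for his-74, -1.137 to 0.043 for his-60, -1.47 to 0.38 for hrde-1, -0.71 to 3.67 for Y69H2.14, -2.94 to 0.46 for col-152, -0.32 to 2.94 for flp-12, -0.90 to 4.53 for snet-1, -1.29 to 0.31 for che-10, -0.93 to 0.005 for dyf-7 and -0.91 to 0.23 for ncl-1. Signed -log10 p of camera (positive for higher in FAS43) in embryos ranged from -14.78 to 0.28 for replicative histone genes, -8.04 to 2.44 for chromatin and small RNA silencing factors, -0.25 to 20.54 for cuticle collagens, -15.87 to 10.61 for oocyte and germline genes, -10.51 to 1.56 for ciliary genes, -0.44 to 7.07 for C-type lectins, -3.78 to 0.56 for nucleolar and ribosome biogenesis genes and -5.67 to 2.72 for DNA damage response and apoptosis genes. In L1 it ranged from -6.66 to 2.22 for replicative histone genes, -4.94 to 0.01 for osmotic stress response and -10.87 to 1.09 for neuropeptides. Of single list results over all alternatives, 20 lost and 34 gained the call in embryos, and 32 lost and 18 gained it in L1. A further 11 list results in embryos and 3 in L1 turned direction. The estimated correlation alone took the call from all 11 lists called in embryos and all 18 called in L1. Causes of the other changes were not tested. Alternatives for normalized values were not run, since raw counts were deposited.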

Other observations

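The tests on heat shock genes were chosen only after their values were seen. Ribosomal protein genes, which encode the proteins of the ribosome, were positive for 69 of 82 members in embryos, with a median log2 fold change of 0.13 (camera adjusted p = 0.394), and negative for 81 of 82 in L1, with a median of -0.29 (camera adjusted p = 0.085). Neither passed the test, and in L1 the signed -log10 p of the list ran from -9.5 without N2 replicate 1 to 9.39 without N2 replicate 2, past the threshold in either direction. Muscle genes had a median of -0.22 in embryos (camera adjusted p = 0.394) and -0.26 in L1 (camera adjusted p = 0.06). Molting genes had a median of -0.41 in embryos, with 30 of 40 members negative, and 0.08 in L1 (camera adjusted p = 0.249). The direction of muscle genes in embryos, and of molting genes in both stages, depended on which library was left out.

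A lower level of heat shock genes in FAS43 at 20 °C was weighed against a single high N2 library. In embryos the median log2 fold change of hsp-70, F44E5.4 and F44E5.5 was -0.2 without N2 replicate 2, so that library may be the source of the difference there. In L1 the same held for F44E5.4 and F44E5.5, with a median of -0.66 without N2 replicate 2, while hsp-16.2 stayed open at -1.32 and hsp-16.41 argues against a single high library, at -2.42 without it and between -2.95 and -2.40 without any one library. Handling shared by libraries numbered 2 predicted a rise in FAS43 too, but there the median log2 ratio of replicate 2 over 1 was -1.12 in L1. In embryos it was -0.12, 0.2 and 0 for hsp-70, F44E5.4 and F44E5.5 in FAS43. In N2 that ratio for F44E5.4 and F44E5.5 was 2.7 and 2.69 in embryos and 2.6 and 2.58 in L1, but 0.42 for hsp-16.41 in L1. The test cannot decide, since it assumes that FAS43 responds to handling as N2 does, which was not tested. A genotype effect on hsp-16.41 and hsp-16.2 in L1 stays among the open explanations, untested beyond these libraries.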
